A study of Danio rerio with 16 samples.

How the data were processed

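Whole, dechorionated wild-type zebrafish embryos from crosses among AB/WIK hybrid parents were exposed to all-trans retinoic acid (RA), to the retinoic acid antagonist AGN193109 or to the solvent dimethyl sulfoxide (DMSO). RA is the vitamin A derivative that activates the retinoic acid receptors, and AGN193109 is a synthetic antagonist of those receptors. Per the labels, 4 independent samples were made for each of 4 groups, which gives 16 arrays: DMSO, RA at 0.33 µM, the antagonist at 10 µM and the antagonist at 1 µM. Embryos were collected at 11 hours post fertilization (hpf). Exposure to DMSO and to the antagonist began at 5.25 hpf and lasted 5.75 hours, whereas exposure to RA began at 6.5 hpf and lasted 4.5 hours. The RA samples therefore differed from their solvent controls in the time of exposure as well. Compounds were diluted 1:50 from stocks in DMSO, which gives the 2% DMSO of the solvent controls. The sample titles and the series design give the doses in µM and the protocol gives them in mM; the µM values were used. The titles spell the compound AGN193019, and the series design and protocol AGN193109; the second spelling was used. A description field about early nuclear cycles does not describe embryos at 11 hpf and was not used. Groups and replicate numbers were taken from the sample titles.

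The deposited values are 1 intensity per probe set and array on a linear scale, made with GCRMA per the submitters' processing notes, which give no version. GCRMA corrects the background with the probe sequences, normalizes between arrays and summarises the probes of each probe set. Whether the submitters scaled the values further is not given in the sources used here. The deposited intensities hold 15617 probe sets with a lowest value of 2. Array medians ran from 72.8 to 78.3, so no array stood apart in overall brightness, and between 72.8% and 76.8% of the probe sets of an array lay above 16. The number of arrays limits the precision. The values hold no probe or scanner data, scan dates or slide numbers, so batches of that kind were not analysed here.

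Log2 of the deposited intensities was used throughout. The 115 Affymetrix control probe sets were left out, and a probe set was tested when it exceeded log2 4 on at least 4 of the 16 arrays, which left 11843. The 4 group means were fitted to all 16 arrays in 1 linear model with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 12 residual and 4.45 prior degrees of freedom). Each comparison was tested two-sided, and p-values were adjusted by the Benjamini-Hochberg method within the comparison. A probe set was called at an adjusted p under 0.05. Fold changes are differences of group means of log2 intensity with the standard error (SE) of the model. Where all 4 arrays of the lower group lay at or below log2 4, the fold is given as a bound against log2 4, written as at least N-fold. The signal of 1 probe set was not compared with that of another.

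Probe sets were named through the platform annotation, with symbols updated by Entrez number through the gene table of assembly GRCz12tu. In the table, 10802 probe sets had 1 symbol, 135 had several and 4680 had none; the update by Entrez number matched 10718 and changed 1 symbol. Probe sets with several symbols were not named. Of the tested probe sets, 8659 had 1 symbol, for 7118 genes. A gene is represented by its probe set with the highest mean over all 16 arrays. A near-identical paralogue can bind to the same probes, which the values cannot resolve.

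The genes named were taken by a rule written before the data were examined. For each comparison with DMSO, the rule took the 10 largest rises and the 10 largest falls among calls in which no treated array overlapped a DMSO array. It took up to 4 members of each gene list with the smallest adjusted p and any member called. It took, of the opposite calls in each direction, the 15 genes with the largest value of the smaller of both fold changes, and the 5 largest differences each way between the antagonist doses. It always took cyp26a1, dhrs3a, aldh1a2, hoxb1b, hoxb1a, hoxa1a, hoxb5a, hoxb5b, hoxb6b, hnf1ba, egr2b, meis3, nr2f5, gbx2, otx2b, cdx4, nrip1a, rarab, tbxta and myod1. Of these, hoxb1b, hnf1ba and nrip1a were not named by the annotation used here and hoxa1a did not pass the filter. The rule took 227 tested genes, of which 87 are described. That selection was made for length after the values had been seen, and it left out some list members whose calls ended when 1 array was left out. For leaving out 1 array, counts over all genes of the rule are therefore given beside it.

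The 21 gene lists were fixed before the data were examined and cover RA metabolism, retinoid receptors, hox genes of groups 1 to 5 and of groups 6 to 13, hindbrain patterning, forebrain with eye and midbrain, segmentation, muscle, axial mesoderm, endoderm, heart, blood, kidney, neural crest and placodes, neurogenesis, epidermis, the yolk syncytial layer, stress, the cell cycle, signalling pathways and reference genes. Of 486 symbols in the lists, 342 genes were measured, 5 of them through a synonym. Lists were tested with limma's camera with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 21 lists. The test was repeated with a correlation estimated from the arrays, and with fry, which asks whether a list moves on balance in 1 direction.

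Samples of a group carry replicate numbers 1 to 4. Deviations from the group means correlated between DMSO and RA arrays of the same number at 0.13, 0.27, 0.34 and 0.15. By the criterion of over 0.1 in every pair, the numbers pair those 2 groups. The link is weak, as only 2 of the 4 DMSO arrays correlated best with the RA array of their own number. Between RA and the antagonist at 10 µM, 3 of 4 did so. This pairing comes from the data, since the labels state no shared clutch or day. The numbers met the criterion for no other pair of groups, which does not exclude a link by number there. A fit with the replicate number as a block was run for all comparisons. Chance splits of the arrays, simulated groups without changes that share the DMSO arrays, and a division of the DMSO arrays 2 and 2 were used where comparisons share controls.

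The procedure was tested on simulated data drawn from the means and spreads of the 11843 tested probe sets with known changes. For RA against DMSO, it recovered 23.5% of changes of 0.5, 85.5% of changes of 1 and 100% of changes of 2 on the log2 scale, and 5.6% of its calls were false. For the antagonist at 10 µM the shares were 22.4%, 90% and 100%, with 5.1% false, and at 1 µM they were 17.6%, 91.9% and 98.7%, with 5.6% false. The simulated probe sets were independent of each other, which real ones are not. Alternatives to the filter, scaling, variance model, set of arrays, threshold, list test and replicates were tried, and each array was left out in turn.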

Results

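Gene expression was measured on Affymetrix zebrafish arrays in whole embryos at 11 hpf, the early somite stage, after exposure to RA, to the RA receptor antagonist AGN193109 or to DMSO. Each of the 4 groups held 4 independent samples (n = 4 per group throughout). The 16 arrays had similar signal distributions, with median intensities of 72.8 to 78.3. Arrays of the same group correlated with each other at a mean r of 0.976 to 0.989 across probe sets. The antagonist at 1 µM held the lowest of these values (0.976 to 0.978, against 0.978 or more in the other groups). Its replicates 1 and 4 correlated with arrays of other groups at 0.967 and 0.966 and its replicates 2 and 3 at 0.978, while RA arrays did so at 0.953 to 0.965. No columns were identical, and the closest arrays, replicates 1 and 3 of the antagonist at 10 µM, differed by a median of 0.13 on the log2 scale. The series asks how embryonic gene expression responds when RA signalling is raised or blocked during gastrulation and early somitogenesis.

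To find which genes responded to excess RA, the RA arrays were compared with the DMSO arrays. Most anterior hox genes rose, and most genes of the forebrain, eye and midbrain fell. The largest rise was that of hoxb5a (log2 fold change 5.46 ± 0.21 SE, adjusted p = 1.52e-11), followed by fgg, a fibrinogen chain gene (4.83 ± 0.21), hoxa4a (4.74 ± 0.16) and hoxb5b (4.70 ± 0.21). The enzyme genes dhrs3a, which encodes a retinaldehyde reductase, and cyp26a1, which encodes an RA-degrading cytochrome, rose by 3.91 ± 0.17 (adjusted p = 8.58e-11) and 3.47 ± 0.27 (adjusted p = 8.72e-08). The deepest falls were those of the hindbrain segment gene egr2b, at least 19.8-fold lower (adjusted p = 2.99e-12), and irx7, which fell by 4.99 ± 0.30.

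In total 681 of the 11843 tested probe sets were called, 377 higher and 304 lower, of which 200 and 166 changed at least 2-fold. They stand for 227 named genes that were higher and 222 that were lower, and 167 called probe sets carried no single symbol. The 4 RA arrays lay beyond all 4 DMSO arrays for 10.1% of all tested probe sets, against the 2.86% that chance gives for 4 against 4. The other large rises were those of hoxa5a, at least 15.2-fold higher, hoxb4a (3.83 ± 0.18), hoxa3a (3.62 ± 0.17) and the retinoid X receptor gene rxrga (3.51 ± 0.15). The other large falls were those of the neural and eye genes mab21l2, at least 11.6-fold lower, dmbx1a (-4.44 ± 0.19) and six7 (-4.29 ± 0.42). Also among them were olig3, at least 8.89-fold lower, and the midbrain-hindbrain genes her5 (-4.35 ± 0.28) and en2a, at least 9.28-fold lower. The rest were sox1a (-3.76 ± 0.18) and hoxa9b, at least 8.27-fold lower. Second probe sets fell less for six7 (-1.21), olig3 (-0.78) and sox1a (-1.79), and by a similar size for dmbx1a (-4.06), all of them called.

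Among 12 measured genes of RA metabolism and feedback, 5 rose and 3 fell (5 and 4 adjusted over the list alone). The list as a whole passed no camera test (adjusted p = 0.416), whereas fry gave an adjusted p of 0.00127 in the higher direction. Besides dhrs3a and cyp26a1, the transcriptional corepressor gene nrip1b rose by 2.09 ± 0.21 and the RA-binding protein gene crabp2a by 0.77 ± 0.18. The retinol-binding protein receptor gene stra6 was at least 6.58-fold lower and cyp26c1 at least 2.03-fold lower. The RA-synthesising enzyme gene aldh1a2 fell by 1.27 ± 0.29 (adjusted p = 0.00973). The remaining rise, of cyp26b1 (0.92 ± 0.23, adjusted p = 0.0199), lost its call without DMSO replicate 1, 3 or 4 or RA replicate 2 or 4 (adjusted p from 0.0598 to 0.0721). That is the probe set used for the gene, 1 of 4. The others were called as well, with adjusted p from 0.000635 to 0.00521 on all arrays. Of 6 retinoid receptor genes, raraa rose by 1.44 ± 0.13 together with rxrga, rarga fell by 1.99 ± 0.20, and rarab had 0.38 ± 0.16 (adjusted p = 0.266); adjusted over the list alone, 3 rose and 1 fell. The receptor list had an adjusted p of 0.0737, which fell to 0.0389 without RA replicate 4.

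The hox genes of paralogue groups 1 to 5, which pattern the hindbrain and anterior trunk, rose as a list, with 12 of 16 measured genes higher and 1 lower (13 and 1 adjusted over the list alone; camera adjusted p = 1.57e-33, and 0.000439 with an estimated correlation). The gene that fell was hoxa2b (-1.34 ± 0.16). Of 19 genes of groups 6 to 13, 4 rose and 5 fell (4 and 7 adjusted over the list alone), and the list had an adjusted p of 0.0870. Leaving out DMSO replicate 3 or RA replicate 2 brought that to 0.00938 or 0.0298, in the lower direction. The genes that rose belonged to groups 6 and 8, such as hoxb6b (3.09 ± 0.19), hoxb6a (2.68 ± 0.33) and hoxb8a (2.06 ± 0.28). The genes that fell belonged to groups 9 to 11, such as hoxa9b and hoxd9a (-3.02 ± 0.18).

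**Figure D1:**
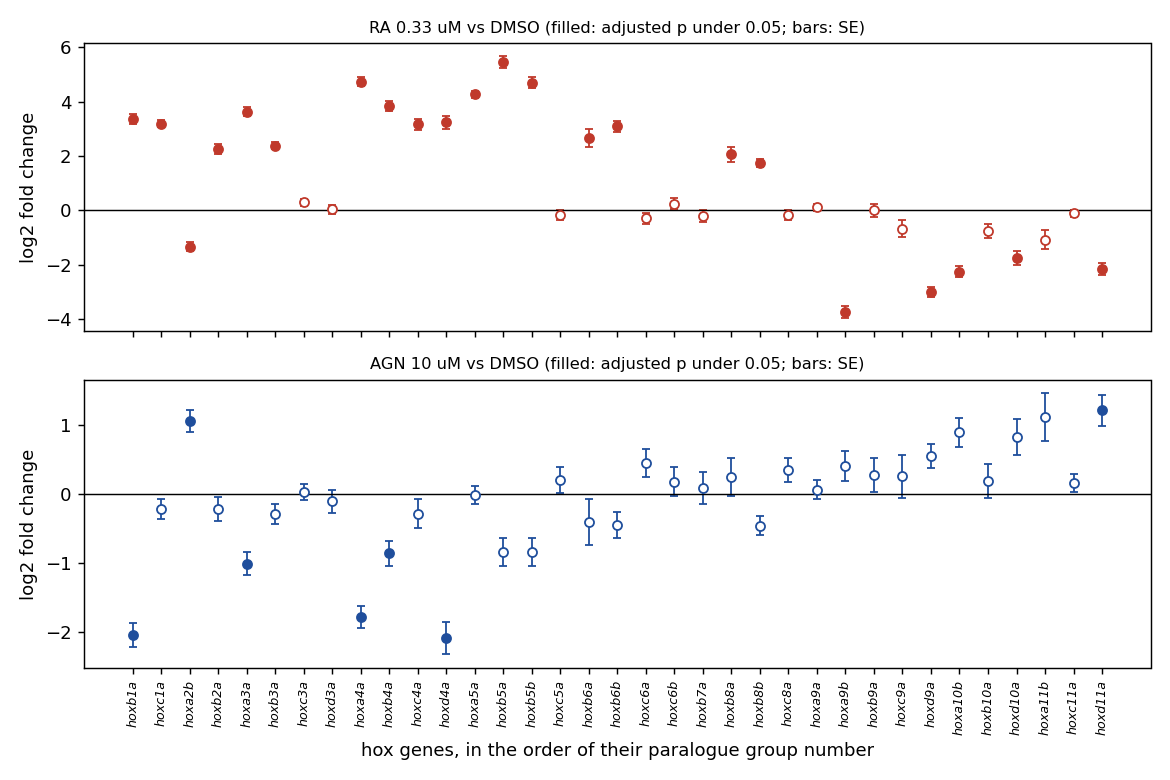
Log2 fold change against DMSO of the 35 measured hox genes, ordered by paralogue group number, for RA (upper panel) and the antagonist at 10 µM (lower panel; the vertical scales differ). Points are model estimates from 4 arrays per group with SE bars, filled where the adjusted p was under 0.05; under RA, 12 of 16 genes of groups 1 to 5 rose, while 5 of 11 genes of groups 9 and above fell.

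Anterior neural genes fell as a list: 22 of 25 measured genes of the forebrain, eye and midbrain were lower and 0 higher (the same counts adjusted over the list alone; camera adjusted p = 1.23e-40, and 0.000439 with an estimated correlation). Examples were otx1 (-3.52 ± 0.25), six3b (-3.17 ± 0.29) and otx2b (-2.65 ± 0.33). Of 26 hindbrain patterning genes, 7 rose and 6 fell (8 and 8 adjusted over the list alone), with an adjusted p of 0.809 for the list, whose median of 0.11 and mean of -0.31 differ in sign. The genes meis2a (2.55 ± 0.22), meis3 (1.44 ± 0.18) and meis1b (1.22 ± 0.13), which encode hox cofactors, rose, and gbx2 (-3.36 ± 0.24) and irx1a (-2.92 ± 0.14) fell. The call of nr2f5 (0.54 ± 0.15, adjusted p = 0.0457) was lost when any of 7 of the 8 arrays was left out (adjusted p from 0.0623 to 0.159); the exception was RA replicate 2. The trunk gene cdx4 had 0.01 ± 0.13 (adjusted p = 0.995).

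Neural crest and placode genes fell as a list, with 2 of 20 higher and 10 lower (3 and 11 adjusted over the list alone; camera adjusted p = 5.34e-05, and 0.0165 with an estimated correlation). The placode genes foxi1 (-2.97 ± 0.22) and dlx3b (-1.22 ± 0.17) fell, as did zic2a (-1.87 ± 0.20). Crest genes went both ways: sox10 (1.06 ± 0.21) and crestin (1.06 ± 0.15) rose, and twist1a (-1.29 ± 0.24) and foxd3 (-0.64 ± 0.10) fell. A further zic2a probe set gave -0.67, with an adjusted p of 0.235. Of 23 neurogenesis genes, 2 rose and 5 fell (4 and 8 adjusted over the list alone, list adjusted p = 0.127). Among them were isl2a (-2.29 ± 0.21), isl1a (-2.21 ± 0.24), sox2 (-0.95 ± 0.12) and olig2 (1.11 ± 0.22). Second probe sets gave a smaller fall for isl1a (-0.94) and a similar one for sox2 (-1.09), both called.

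Genes of axial mesoderm fell as a list, with 1 of 17 higher and 6 lower (1 and 10 adjusted over the list alone; camera adjusted p = 3.33e-05, and 0.0104 with an estimated correlation). The prechordal plate gene gsc fell by 3.07 ± 0.32, the notochord gene noto by 1.40 ± 0.21 and chrd by 0.70 ± 0.13, while tbxta had -0.15 ± 0.10 (adjusted p = 0.639). Segmentation genes also fell as a list, with 1 of 17 higher and 6 lower (1 and 7 adjusted over the list alone; camera adjusted p = 7.05e-05, and 0.0298 with an estimated correlation). The presomitic mesoderm genes msgn1 (-2.29 ± 0.15), tbx16 (-1.25 ± 0.13) and tbx16l (-1.04 ± 0.14) fell. The muscle list passed no camera test (0 of 12 higher and 1 lower, also adjusted over the list alone; adjusted p = 0.751), although 3 genes had an unadjusted p under 0.05 and fry for changes in either direction gave an adjusted p of 0.0321, and myod1 had -0.16 ± 0.10 (adjusted p = 0.591).

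Endoderm and blood lists passed the preset test and not the one with an estimated correlation. Of 9 endoderm genes, 1 fell and 0 rose (4 and 0 adjusted over the list alone; adjusted p = 0.0208, and adjusted p = 0.336 with an estimated correlation), the chemokine receptor gene cxcr4a (-1.70 ± 0.22). Of 10 blood and endothelial genes, 1 rose and 3 fell (1 and 3 adjusted over the list alone; adjusted p = 0.0373, and adjusted p = 0.266 with an estimated correlation), with tal1 at least 4.00-fold lower and drl at -1.92 ± 0.16. Without DMSO replicate 2 or RA replicate 4 both lists missed the threshold (adjusted p of 0.0520 and 0.0673 for endoderm, 0.0520 and 0.0539 for blood). The blood list also missed it without DMSO replicate 1 (0.0550) and with the replicate block (0.0567), and the endoderm list without the filter (0.0851).

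The other lists passed no camera test under RA. Heart genes gave 2 higher and 3 lower of 10 (the same adjusted over the list alone; adjusted p = 0.441), with hand2 at 1.03 ± 0.16 and nkx2.7 at -1.97 ± 0.23. Kidney genes gave 1 and 1 of 8 (3 and 1 adjusted over the list alone; adjusted p = 0.0870), the fall being that of pax2a (-1.66 ± 0.19). The kidney list reached 0.0487 without RA replicate 3 and 0.0468 without the filter. Of 12 yolk syncytial layer genes 1 fell, also adjusted over the list alone, apoa4b.1 (-2.63 ± 0.18); the list had an adjusted p of 0.234, or 0.0359 without DMSO replicate 3. Signalling genes gave 6 higher and 7 lower of 34 (8 and 10 adjusted over the list alone; adjusted p = 0.377), with szl (-2.58 ± 0.37), lft1 (-2.54 ± 0.28), sp5a (-1.97 ± 0.24) and dusp6 (0.99 ± 0.15). A second dusp6 probe set had 0.60 with an adjusted p of 0.0595. For epidermis, the cell cycle and reference genes, limma called 0 of 24, 0 of 25 and 0 of 16 genes, also adjusted over the list alone, and 7, 0 and 1 had an unadjusted p under 0.05. For stress it called 1 of 22, also adjusted over the list alone. These lists had adjusted p-values of 0.809, 0.809, 0.871 and 0.809. In all, 7 lists passed, and 6 of the 35 splits of the 8 arrays gave 7 or more, as did 2 of the 8 splits that part all numbered pairs of DMSO and RA. Of the 131 calls among the genes of the rule, 117 remained calls without any single array.

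To find which genes depend on RA receptor activity at this stage, the arrays of the antagonist at 10 µM were compared with the DMSO arrays. The gene with the deepest fall was dhrs3a, at least 7.20-fold lower (adjusted p = 6.34e-09). Of the genes with the next largest falls, hoxd4a was 4.28-fold lower (adjusted p = 0.000100), hoxb1a fell by 2.05 ± 0.18 (adjusted p = 8.71e-06), meis3 by 2.01 ± 0.18 (adjusted p = 1.17e-05), hoxa4a by 1.78 ± 0.16 and meis2a by 1.72 ± 0.22. The genes wnt11 (-1.68 ± 0.17), nrip1b (-1.60 ± 0.21), rxrga (-1.48 ± 0.15) and the proneural gene neurog1 (-1.47 ± 0.22) completed the 10 largest falls. The 7 named genes that were higher rose by less: tbx1 by 1.24 ± 0.20, hoxd11a by 1.21 ± 0.22, cyp26b1 by 1.18 ± 0.23, hoxa2b by 1.06 ± 0.16, tfap2b by 0.75 ± 0.16 and lhx9 by 0.71 ± 0.14, while hey2 was 2.14-fold higher (adjusted p = 0.0119).

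**Figure D2:**
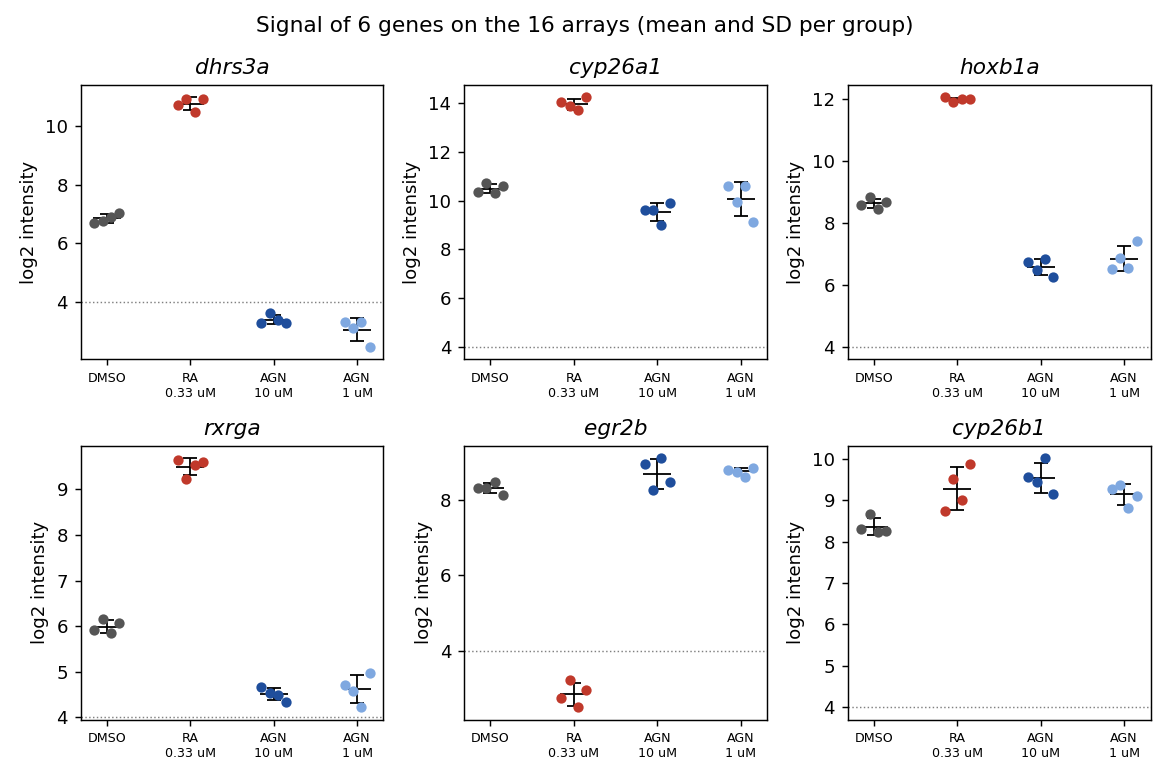
Log2 intensity of 6 genes on each of the 16 arrays; dots are arrays, horizontal marks and bars are group means and SD (n = 4), and the dotted line is the filter at log2 4. The 4 genes dhrs3a, cyp26a1, hoxb1a and rxrga were highest under RA and had lower means under both antagonist doses than in DMSO, egr2b lay below the filter under RA alone, and cyp26b1 had a lower mean in DMSO than in the other groups.

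In total 47 probe sets were called, 10 higher and 37 lower, of which 7 and 22 changed at least 2-fold; they stand for 7 higher and 24 lower named genes. At an unadjusted p under 0.05 the number was 610, close to the share of 0.05 of all tested probe sets that chance alone gives. The 4 antagonist arrays lay beyond all 4 DMSO arrays for 5.45% of all tested probe sets, where chance gives 2.86%. The RA-degrading enzyme gene cyp26a1 had -0.97 ± 0.27 with an adjusted p of 0.314. The genes hoxb5a (-0.84 ± 0.21, adjusted p = 0.145), hoxb5b (-0.84 ± 0.21, adjusted p = 0.145), egr2b (0.39 ± 0.18, adjusted p = 0.949) and aldh1a2 (0.33 ± 0.29, adjusted p = 1.00) were not called either. The 47 calls became 29 without DMSO replicate 1 and 30 without replicate 1 of the antagonist, and 255 with array weights, of which 118 (46.3%) were higher, against 21.3% of the 47.

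Hox genes of groups 1 to 5 fell as a list, with 5 of 16 lower and 1 higher (7 and 1 adjusted over the list alone; camera adjusted p = 6.72e-12, and 0.0314 with an estimated correlation). Besides those above, hoxa3a (-1.01 ± 0.17) and hoxb4a (-0.86 ± 0.18, adjusted p = 0.0472) were lower. Groups 6 to 13 rose as a list, with 1 of 19 higher and 0 lower (5 and 1 adjusted over the list alone; adjusted p = 2.72e-05, but adjusted p = 0.319 with an estimated correlation). RA metabolism and feedback fell as a list, with 1 of 12 higher and 2 lower (2 and 4 adjusted over the list alone; adjusted p = 0.00240, and 0.0314 with an estimated correlation). The muscle list (adjusted p = 0.0219, higher; adjusted p = 0.319 with an estimated correlation) and the endoderm list (adjusted p = 0.0330, lower; adjusted p = 0.410 with an estimated correlation) passed with 0 of 12 and 0 of 9 genes called by limma, also adjusted over the list alone, and 3 and 1 at an unadjusted p under 0.05. The muscle list missed the threshold without replicate 1 or 3 of the antagonist (adjusted p of 0.0507 and 0.116). The endoderm list missed it without DMSO replicate 2 (0.0947) and without replicate 1 or 3 of the antagonist (0.0507 and 0.343), as well as after quantile normalization (0.0550) and without the filter (0.116).

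The remaining lists gave adjusted p-values of 0.0567 or more. Of the heart list, 2 of 10 genes were higher, tbx1 and hey2, and of the hindbrain list 3 of 26 were lower. The forebrain, eye and midbrain list, 22 of whose genes fell under RA, had 0 of 25 genes called by limma (2 at an unadjusted p under 0.05; list adjusted p = 0.509), although the list reached 0.0454 without DMSO replicate 2. Of 7 rises, tbx1 and hoxa2b stayed called without any single array. The call of hey2 was lost without DMSO replicate 2 or 4 (adjusted p of 0.0553 and 0.0589). That of hoxd11a was lost without DMSO replicate 1 or 3 or replicate 1 or 3 of the antagonist (0.0562 to 0.0766). The cyp26b1 call was lost without DMSO replicate 1, 3 or 4 or replicate 1, 2 or 3 of the antagonist (0.0667 to 0.121). Its other probe sets were called too, with adjusted p from 0.00262 to 0.0149 on all arrays. The lhx9 call was lost without DMSO replicate 1 or 3 or any replicate of the antagonist (0.0658 to 0.121). For tfap2b and hoxb4a it was lost without any array but DMSO replicate 3 (0.0617 to 0.208 and 0.0660 to 0.212). Without the filter, hoxb4a had an adjusted p of 0.0596. Over all genes of the rule, 16 of 26 calls remained without any single array. In all, 5 lists passed, and 8 of the 35 splits of the 8 arrays gave 5 or more; without DMSO replicate 1 the number was 8, with segmentation, heart and the yolk layer added (each 0.0434). Heart passed also without DMSO replicate 2 or replicate 3 or 4 of the antagonist (0.0314, 0.0183 and 0.0477), and the yolk layer without DMSO replicate 2 or replicate 4 of the antagonist (0.0314 and 0.0287). Retinoid receptors passed without DMSO replicate 3 or replicate 1 of the antagonist (0.0177 and 0.0460), the cell cycle without DMSO replicate 4 or replicate 2 of the antagonist (0.0176 and 0.0407) or without the filter (0.0123), segmentation without that replicate 2 (0.0407) and signalling without DMSO replicate 3 (0.0428).

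The antagonist at 1 µM was compared with DMSO to see whether a lower dose acts on the same genes. The largest fall was again that of dhrs3a, at least 7.20-fold lower (adjusted p = 1.46e-09). The next were hoxb1a (-1.79 ± 0.18, adjusted p = 9.42e-05), hoxa4a (-1.49 ± 0.16), rxrga (-1.37 ± 0.15), neurog1 (-1.34 ± 0.22), meis3 (-1.20 ± 0.18) and wnt11 (-1.08 ± 0.17). The falls of tshz1 (-1.01 ± 0.18), hoxa3a (-0.91 ± 0.17) and znf503 (-0.79 ± 0.15) completed the 10 named genes that were lower. The 3 that were higher were tbx15 (1.35 ± 0.22), tbx1 (1.21 ± 0.20) and zic6 (0.80 ± 0.13).

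In total 17 probe sets were called, 3 higher and 14 lower, and 744 had an unadjusted p under 0.05. By chance alone a share of 0.05 of all tested probe sets would have it. Of the 35 splits of these 8 arrays into 4 and 4, 3 gave as many calls. The calls numbered 9 without DMSO replicate 1, 11 without DMSO replicate 2 and 7 in a fit of only these 2 groups. Without replicates 1 and 4 of this group, which correlated least with other groups, they numbered 15; these were chosen after seeing the data. The 4 antagonist arrays lay beyond all 4 DMSO arrays for 249 of the 11843 tested probe sets, a smaller share than the 2.86% that chance gives. The calls of dhrs3a, hoxb1a, hoxa4a, rxrga, meis3 and wnt11 remained without any single array. The call of neurog1 was lost without replicate 4 of the antagonist (adjusted p = 0.0519). The tbx1 call was lost without that array or DMSO replicate 1 or 4 (0.0521 to 0.0722), and the tbx15 call without DMSO replicate 1 or 3 or replicate 1 of the antagonist (0.0524 to 0.0596). The zic6 call was lost without any DMSO array or replicate 1 or 2 of the antagonist (0.0561 to 0.0800). The tshz1 call was lost without DMSO replicate 1, 2 or 3 or replicate 1, 2 or 3 of the antagonist (0.0561 to 0.116). The hoxa3a call was lost without DMSO replicate 1, 2 or 4 or replicate 2 or 3 of the antagonist (0.0785 to 0.148). The znf503 call was lost without any array but replicate 1 of the antagonist (0.0519 to 0.148).

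Hox genes of groups 1 to 5 fell as a list at 1 µM, with 3 of 16 lower and 0 higher (8 and 1 adjusted over the list alone; adjusted p = 3.35e-09, but adjusted p = 0.145 with an estimated correlation). Groups 6 to 13 were higher, with 0 of 19 called by limma (also adjusted over the list alone; 5 at an unadjusted p under 0.05; list adjusted p = 0.0317, but adjusted p = 0.571 with an estimated correlation). The heart list was higher, with 1 of 10 called, tbx1 (2 adjusted over the list alone; adjusted p = 0.0317, but adjusted p = 0.164 with an estimated correlation). Groups 6 to 13 missed the threshold without DMSO replicate 3 (0.466) and without replicate 2 or 4 of the antagonist (0.402 and 0.0519), as well as after quantile normalization (0.0514). The heart list missed it without DMSO replicate 4 (0.0729) and without replicate 2 or 3 of the antagonist (0.0899 and 0.205). In all, 3 lists passed, and 15 of the 35 splits gave 3 or more; the number was 1 without replicate 2 of the antagonist and 5 without replicate 4, which added retinoid receptors, segmentation and blood. Segmentation passed also without DMSO replicate 1 (0.0169), without the filter (0.0322), with the mean of all probe sets of a gene (0.0379) and with the replicate block (0.0429).

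The doses of the antagonist were compared directly. Only 1 probe set was called, which has no gene name in the annotation used here. It was at least 6.16-fold lower at 10 µM than at 1 µM (adjusted p = 1.88e-06). At an unadjusted p under 0.05 limma gave 1056 probe sets, where chance alone gives a share of 0.05 of those tested. Of the 35 splits of these arrays, 3 gave at least 1 call. For dhrs3a both groups lay below the filter, so no difference is given. The difference between 10 µM and 1 µM was -0.26 for hoxb1a (95% confidence interval -0.63 to 0.11). It was -0.11 for rxrga (-0.43 to 0.20), -0.80 for meis3 (-1.19 to -0.41; adjusted p = 0.395) and -1.01 for hoxd4a (-1.50 to -0.52; adjusted p = 0.395). The intervals of single genes are not adjusted for the number of genes. Of these genes, only hoxd4a was among the largest dose differences taken by the rule. Others so taken included aldocb, atp5l, ciarta, ero1a, h2ax, slc16a3b and szl, and none was called. Log2 signal of ciarta was 6.004 to 8.597 at 10 µM and 5.099 to 7.095 at 1 µM, and for every replicate number it was higher at 10 µM. That of aldocb was 5.434 to 6.842 and 5.535 to 8.079. The genes above therefore do not show where the doses differed most. All 47 probe sets called at 10 µM had the same sign at 1 µM, and 46 of them a smaller change; they were picked for their change at 10 µM, which favours a larger value there. Of the 17 called at 1 µM, all 17 had the same sign at 10 µM, and 3 a smaller change there. The shared DMSO arrays alone favour the same sign: of as many probe sets with the lowest p in groups simulated without change, a mean of 41.6 of 47 and 14.9 of 17 had it. With calls made against 2 DMSO arrays and signs taken against the other 2, 132 of 132 calls at 10 µM and 42 of 43 at 1 µM had the same sign at the other dose, summed over 6 divisions. Without replicate 2 or 3 of the antagonist at 1 µM, the calls numbered 3 and 2, all lower at 10 µM. Of the 21 lists, 0 differed by camera, by camera with an estimated correlation or by fry.

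Both doses called 15 probe sets in the same direction, 1 higher and 14 lower, and 0 in opposite directions. Independent lists of these lengths would share 0.0025 higher and 0.044 lower. Both comparisons share the DMSO arrays. Groups simulated without change against those arrays shared 0 calls, but they are built to hold hardly any calls. That 0 is therefore no baseline for the overlap of real calls. With the DMSO arrays divided 2 and 2, the doses shared 5 to 7 calls. Fold changes of the doses correlated across probe sets, which are not independent replicates, at r = 0.457, against a simulated mean of 0.463 (-0.962 to 0.957) without any change. The covariance was 0.0234 against a simulated 0.0209, and 60.4% of all tested probe sets had the same sign at both doses, against a simulated 66.4%. The number of shared calls was 9 without DMSO replicate 1.

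To see whether agonist and antagonist acted on the same genes in opposite directions, calls under RA and under the antagonist at 10 µM were set side by side. The exposures differed in length and in dose, so sizes are not matched. Of the 47 probe sets called with the antagonist, 40 were called in the opposite direction with RA: 35 were higher with RA and lower with the antagonist, and 5 were lower with RA and higher with the antagonist. Among the former were dhrs3a, hoxd4a, hoxb1a, hoxa4a, meis2a, wnt11, nrip1b, rxrga, tshz1 and znf503. The latter were tbx1, hoxd11a, hoxa2b, hey2 and lhx9. Under RA, tbx1 was at least 4.09-fold lower, hoxd11a at least 1.49-fold lower and lhx9 at least 1.37-fold lower, and hey2 fell by 1.03 ± 0.19. Called in the same direction were 5 probe sets, the 4 of cyp26b1, which were higher, and the unnamed probe set that differed between the antagonist doses, which was at least 8.39-fold lower with either compound. The antagonist calls of neurog1 and tfap2b were not called with RA, where they had 0.76 ± 0.22 (adjusted p = 0.0610) and -0.46 ± 0.16 (adjusted p = 0.126).

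**Figure D3:**
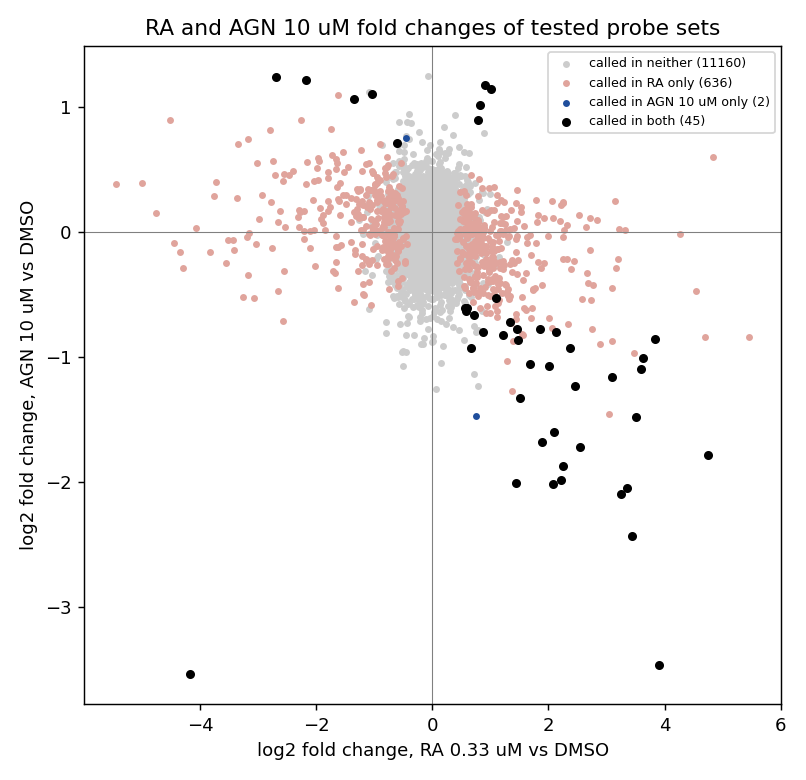
Log2 fold change against DMSO under RA (horizontal) and under the antagonist at 10 µM (vertical) of the 11843 tested probe sets. Black points were called in both comparisons (45), pale red points with RA alone (636), the blue points with the antagonist alone (2) and grey points in neither; 35 of the black points lie at the lower right.

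Independent lists of these lengths would give 1.18 probe sets higher with RA and lower with the antagonist, and 0.257 the other way. Groups simulated without change against the shared DMSO arrays gave 0 opposite calls. Such groups are built to hold hardly any calls, so this 0 is no baseline for the overlap of 2 lists of real calls. With the DMSO arrays divided 2 and 2, the opposite calls numbered 16 to 23. Of the 681 probe sets called with RA, 461 had the opposite sign with the antagonist at 10 µM and 220 the same, against a mean of 591 the same (53 to 681) in groups simulated without change, while 56.1% of all tested probe sets had the same sign, against a simulated 68%. The fold changes correlated across probe sets at r = -0.182, which lies within the range of -0.406 to 0.911 (mean 0.499) simulated without any change, and the covariance was -0.0173 against a simulated 0.0224. The 40 opposite calls became 25 without DMSO replicate 1 and 26 without replicate 1 of the antagonist. RA and the antagonist at 1 µM gave 14 opposite calls and 0 in the same direction.

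Compared directly, 1048 probe sets differed between RA and the antagonist at 10 µM, 567 higher and 481 lower with RA. Of the 21 lists, 8 passed: hox groups 1 to 5 (12 of 16 genes higher and 1 lower; 13 and 1 adjusted over the list alone) and retinoid receptors (3 of 6 higher and 1 lower in both counts) were higher with RA. Forebrain, eye and midbrain (22 of 25 lower and 0 higher in both counts), hox groups 6 to 13 (8 of 19 lower and 4 higher; 10 and 4 adjusted over the list alone), segmentation, axial mesoderm, neural crest and placodes, and the yolk layer were lower. With an estimated correlation 5 remained; retinoid receptors (adjusted p = 0.128), hox groups 6 to 13 (adjusted p = 0.446) and the yolk layer (adjusted p = 0.359) did not.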

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

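The tests of the antagonist dose, of a strain variant and of cross-hybridization were chosen after the values were seen; the tests of a shared batch and of shared DMSO arrays were chosen before their results were.

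The antagonist doses differed in 1 probe set, which has no gene name in the annotation used here. Its log2 signal was 6.53 to 7.38 on DMSO arrays and 6.06 to 7.13 at 1 µM, but 3.15 to 3.93 at 10 µM, with a mean of 2.90 under RA, and the test of 10 µM against 1 µM gave a fitted value of -3.092. As the 10 µM arrays lay below the filter, that value is no exact size, and the bound is at least 6.16-fold lower. For a batch shared by the RA and 10 µM arrays, 0 other probe sets parted those 8 arrays from the other 8 by over 0.5 on the log2 scale. The pairing of RA with 1 µM also gave 0. The 10 that parted the antagonist arrays from the rest hold the treatment itself and are no baseline for a batch. No shift of that size was thus shared by other probe sets, but the count cannot exclude a smaller batch effect. A variant and the dose cannot be told apart. A strain or clutch variant under the probes is open, because the parents were AB and WIK hybrids and the labels name no clutch. The gap of 2.13 between the 2 sets of arrays also exceeds the largest range within a group, 1.07. Such a variant would have to follow the treatment in every sample, as all DMSO arrays (6.53 to 7.38) lay above all RA arrays (2.8 to 3). If DMSO and RA samples of the same number shared a clutch, these values would argue against it, but the labels do not state that. A response to the higher dose of the antagonist, with that fitted value (-3.09) resting on signal below the filter, is open too. A single compound at 2 doses and 1 probe set cannot decide it. Such a response would require that RA and its antagonist both lower the signal, which speaks for caution.

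Single arrays stood apart from the other 3 of their group in 17 of the 352 combinations of gene and group tested, where chance gives about 5%, or 1 in 20. The ratio of the gap to the range is given first and then the log2 value of the array against the others. On AGN 10 µM replicate 2 these were wnt11 (0.947; 5.55 against 6.18 to 6.22), nrip1b (0.917; 5.90 against 6.41 to 6.46) and irx1a (0.926; 7.70 against 8.05 to 8.08). For this dose hoxa2b also stood apart on replicate 3 (0.932; 6.78 against 6.11 to 6.16) and tshz1 on replicate 4 (0.899; 6.93 against 7.22 to 7.25). At 1 µM they were olig3 (0.851; 8.84 against 7.91 to 8.05) and tal1 (0.835; 7.03 against 6.40 to 6.50) on replicate 1, and hoxa5a (0.833; 3.77 against 3.48 to 3.53) on replicate 2. On replicate 4 they were irx1a (0.896; 7.83 against 8 to 8.02) and crestin (0.921; 6.71 against 6.27 to 6.30). In DMSO they were cyp26b1 (0.846; 8.67 against 8.23 to 8.30) and six3b (0.942; 9.36 against 8.71 to 8.75) on replicate 2. On DMSO replicate 3 they were rarga (0.836; 7.46 against 7.99 to 8.09), sox2 (0.857; 10.41 against 10.70 to 10.74) and lft1 (0.856; 9.39 against 9.26 to 9.28). Under RA they were tbx15 (0.854; 4.64 against 3.79 to 3.92) and isl2a (0.883; 3.84 against 4.82 to 4.95), both on replicate 1.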

How the results depend on the processing

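The within-group component as a covariate and the removal of 2 arrays were chosen after seeing the data. For RA against DMSO, the 681 calls stayed between 468 and 804 under the filters, scalings, variance models, block and threshold, and rose to 1194 with array weights and 1050 with the component; the cause was not tested. For the antagonist at 10 µM, the 47 calls became 255 with array weights (cause not tested) and 28 at an adjusted p under 0.01. For 1 µM, the 17 became 7 at that threshold, 7 in a fit of only the 2 groups, which has fewer samples, and 105 with the component. For 10 against 1 µM, the single call became 2 with median centring and 137 with the component. For RA against the antagonist, the 1048 became 1946 with array weights, 667 at the stricter threshold and 1577 with the component. The component was estimated from these arrays, so its p-values are too small. The 40 opposite calls became 117 with array weights and 24 at the stricter threshold. The 15 same calls became 6 in fits of only 2 groups, 7 at the stricter threshold and 30 with the component.

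Leaving out 1 array gave 547 to 655 calls for RA, 29 to 44 and 9 to 17 for the antagonist at 10 and 1 µM, 1 to 3 between doses, 821 to 1039 for RA against the antagonist, 25 to 41 opposite and 9 to 14 same calls. The lists past the threshold ranged over 5 to 9 for RA, 4 to 8 at 10 µM, 1 to 5 at 1 µM and 0 between doses. With fry, 14 lists passed for RA, 3 at 10 µM and 2 at 1 µM; with an estimated correlation 5, 2 and 0 did.

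The replicate block gave 804, 49, 18, 1 and 1205 calls for the 5 comparisons, 41 opposite and 16 same calls, and 6, 6, 4 and 0 lists. Outside DMSO and RA the numbers missed the criterion for pairing, with correlations of same-numbered arrays from -0.46 to 0.76. That does not exclude a link by number. The second component of the variation within groups was negative on every replicate 2 array (-0.398 to -0.162). It was positive on every replicate 3 array (0.051 to 0.532). Among the described genes the block ended the calls of hoxb4a (adjusted p = 0.0592) and tfap2b (0.0745) at 10 µM. Among the lists it ended blood for RA and added heart at 10 µM (0.0447) and segmentation at 1 µM (0.0429). It changed no other call of a described gene or list. Of 146 results for the 87 described genes and the unnamed probe set, 0 reversed under any alternative. In fits of only 2 groups 14 lost a call, and 18 did at the stricter threshold. Under each scaling, without the filter and with the trend and robust model, 1 or 2 did. The 87 genes were selected after the values were seen, and these alternatives were not counted over all 227 genes of the rule. Array weights added 5 calls. With the stricter filter of log2 6, all 138 results still tested kept their side. Quantile normalization ended the endoderm list at 10 µM and hox groups 6 to 13 at 1 µM. Signal near the background limits dim genes, whose folds are given as bounds.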

Other observations

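Tests of the order of the hox genes and of cross-hybridization were chosen after the result was seen; the tests of signal level, of shared DMSO arrays and of other splits of the arrays were chosen before.

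Within groups the arrays varied together in sets of genes. The first within-group component held 31.7% of the variance within groups, and 14 of its 40 leading genes encode subunits of the respiratory chain or the ATP synthase, such as ndufb6, ndufa6, uqcrq and cox6c. The second held 25.6% and was led by the heat shock gene hsp90aa1.2 and slc25a14, with the clock-related genes ciarta and nr1d2b of opposite sign. This second component was negative on every replicate 2 array and positive on every replicate 3 array. Leading genes of the components include members of the lists, such as hspe1, sox19b, hsp90aa1.2 and mki67. Those of the second also include ciarta, aldocb and slc16a3b, which are among the largest differences between the antagonist doses. The genes given here were picked after their values were seen. The signal of the GAPDH 3' control probe set ran from 5.99 on replicate 3 and 6.88 on replicate 1 of the antagonist at 10 µM to 10.1 on replicate 3 at 1 µM.

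Across the 35 measured hox genes, the RA fold change tended to fall and the antagonist fold change to rise with the paralogue group number. That number follows the order of the genes along their clusters. The fall under RA was not steady. The largest RA folds were in groups 4 and 5 (hoxb5a 5.46, hoxa4a 4.74, hoxb5b 4.70), although hoxc5a had -0.18. Those of group 1 were smaller (hoxb1a 3.35, hoxc1a 3.19), and 5 of the 11 genes of groups 9 and above were called lower. For RA, Spearman's rho was -0.64 (permutation p = 6e-05) and Pearson's r -0.63 (p = 9e-05). For the antagonist at 10 µM, rho was 0.63 (p = 7e-05) and r 0.59 (p = 0.00013), and at 1 µM rho was 0.63 (p = 3e-05). Adjusted over these 3 relations, the largest p was 7e-05; hox genes are not independent replicates. Signal level is argued against as the cause, since rho with the mean log2 level held was -0.65 for RA and 0.65 for 10 µM. Without the 2 genes farthest from the median group number, rho was -0.62 and 0.57. A candidate explanation that stays open is a response that differs with cluster position, tested on the same data that showed it. The values under RA do not show a steady gradient within groups 1 to 5.

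The gene cyp26b1, which encodes an RA-degrading enzyme, was higher with both RA and the antagonist. All 4 of its probe sets were called higher in both, by 0.79 to 1.02 with RA and 0.89 to 1.18 with the antagonist at 10 µM, and they had 0.60 to 0.83 at 1 µM. The treatments differed by -0.26 (95% confidence interval -0.74 to 0.22). Low DMSO arrays shared by both comparisons cannot be told apart from a rise of this gene with both compounds. With these arrays divided 2 and 2, the smaller of both folds was never under 0.80 ± 0.28 SE, but every array of both treatments lay above all DMSO arrays for the probe set divided, so the division cannot decide. Cross-hybridization of cyp26a1 RNA is argued against with the antagonist, where cyp26a1 had -0.97 with an upper bound of -0.39, but it could account for the rise with RA, where cyp26a1 rose by 3.47. No biological explanation was tested.

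Other splits of the same arrays bear on whether chance can be excluded. For the 681 calls with RA, 1 of 35 splits, the real one, gave as many, and the highest other gave 27. The real split is always among the 35, so 1 of 35 is the smallest share this test can give. It argues against chance but cannot exclude it, and shares were not adjusted for the number of comparisons. Among the 8 splits that part all 4 numbered pairs of DMSO and RA, the highest other gave 0; the split with 27 set replicates 1 and 3 of both groups against 2 and 4. The same smallest share was reached for the 47 calls at 10 µM (1 of 35, highest other 0). It was also reached for the 1048 between RA and the antagonist (1 of 35, highest other 1). For the 40 opposite calls, 1 of 100 random splits into 3 groups gave as many (highest other 0). For the 15 same calls 2 of 100 did, and the highest other, 16, exceeded the real number. Random splits of this kind mix the treatments, which removes the calls of each comparison as well. They therefore bear on the absence of any effect and do not decide whether 2 lists overlap by chance. For the 17 calls at 1 µM, 3 of 35 splits gave as many, so their number alone does not exclude chance. Of these 17, 15 are the same calls given above, and 14 were called in the opposite direction with RA, where independent lists give 0.446 and 0.0770 in the 2 directions. The highest split gave 573, with DMSO replicate 2 and replicates 1, 2 and 4 of the antagonist on 1 side, which points to a structure of these samples other than treatment. Between doses, 3 of 35 splits gave at least 1 call (highest other 5, with replicates 1 and 3 at 10 µM and 1 and 4 at 1 µM on 1 side), so the number alone does not exclude chance. The probe set called had an adjusted p of 1.88e-06, and its 10 µM and 1 µM arrays were parted by a gap of 2.13, against a largest range of 1.07 within a group. Chance cannot be excluded for the number of lists past the threshold: 7 with RA (6 of 35; highest other 8; 2 of the 8 that part all pairs, highest other 8), 5 at 10 µM (8 of 35; highest other 9) and 3 at 1 µM (15 of 35; highest other 9). Between doses 0 lists passed, which all 35 of 35 splits reach whatever the data (highest other 7), so the splits decide nothing there.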
